A study of Homo sapiens with 6 samples.

How the data were processed

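RNA of NCI-H1299 cells, a human lung cancer line that lacks p53 protein, was measured by RNA sequencing in 6 libraries. The labels put 3 libraries in a wild-type control group, with Puro in their titles, and 3 in a group with FuHsi knocked down, with Sh1 in their titles. The labels do not spell out Puro or Sh1, and nothing in them says that the replicates of a group came from separate cultures. P-values therefore measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was isolated with RNAiso Plus and libraries were made with a TruSeq kit.

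The authors deposited 1 table of whole-number read counts per Ensembl gene, with 1 column per library and no normalization. Per the submitters' processing notes, Trim Galore 0.6.6, STAR 2.7.0d, featureCounts 2.0.1 and DESeq2 1.30.1 were used with the hg38 genome build; their order and settings are not given in the sources used here. The annotation release, the strand setting and the treatment of reads with several alignments are likewise not given in the sources used here. Counts of overlapping genes, of antisense partners and of genes with near-identical copies are therefore uncertain. The percentage of each gene's exonic bases shared with an exon of another gene on either strand was computed from GENCODE v29 on GRCh38, and is given for TYMS, ASNS, RPL17, MTHFD2, AIMP2, WIPI1, VIM and SNHG10, where it is highest among named genes.

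The table held 60617 genes, of which 34312 had a count in at least 1 library. Of the identifiers, 60261 matched a table of gene names and a further 335 matched GENCODE v29 alone; 42335 of all identifiers had a symbol that was not itself an identifier. Biotypes, coordinates, transcript lengths, GC content and 3′ UTRs came from GENCODE v29, which held 17004 of the 17223 tested genes. Library totals ran from 24231515 to 34306849 counts, and all 3 control libraries were deeper than all 3 knockdown libraries. At this depth the common biological coefficient of variation was 4.67%, so small differences of abundant genes pass the test.

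Genes were filtered with filterByExpr of edgeR 4.0.16 at its default minimum count of 10, and libraries were scaled by the trimmed mean of M values (TMM). Differences were tested with edgeR's quasi-likelihood test with robust dispersions in R 4.3.3, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the 17223 genes. A gene was called at an adjusted p under 0.05. Fold changes are knockdown over control on the log2 scale, with a standard error (SE) derived from the test statistic. Library-scaled counts (CPM) are scaled by TMM and given as mean ± SD of 3 libraries. Log2 CPM used a prior count of 2.

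Before the data were examined, 38 gene lists were fixed, together with the tests and the alternatives. Each list was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, and p-values were adjusted over the lists by the Benjamini-Hochberg method. Camera compares a list with all other genes. Alternatives for the lists were a correlation estimated from these libraries and fry, which tests whether a list moves, on balance, one way and does not compare it with other genes. The rule for named genes was fixed at the same time. It took 9 nucleolar and growth genes whatever their values. It took the 10 largest rises and 10 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and groups that did not overlap. It took up to 2 rises and 2 falls per list among called members at that level, or the 2 smallest p-values where none passed, and 3 non-coding genes in each direction. A subset of the genes under the rule is named.

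The gene test was tested on simulated counts drawn from the means, dispersions and library sizes of these libraries. For knockdown against control, with 16862 simulated genes tested, 93 of 100 genes changed by 1 log2 unit and 77 of 100 changed by 0.5 were called in the right direction, and 14 of 16584 unchanged genes were called. A shift of -0.3 given to the cytosolic ribosomal protein list was called by camera, and 0 of the other 36 lists were. Simulated genes were drawn independently, so this run could not test camera on lists whose members are correlated. It also changed few genes. It therefore could not test the scaling or the rate of false calls where 61.6% of tested genes are called, as in the data.

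A scan of all 7-base words compared the fold changes of 11343 protein-coding genes with and without each word in the annotated 3′ UTR, and in the coding sequence. Trends on length, GC content and mean abundance were removed first. The spread expected by chance came from 100 permutations of the genes. In simulated data the scan found 5 of 5 planted words. Trends were fitted as cubic polynomials, and intervals of list medians are 95% bootstrap intervals over members from 2000 draws.

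Alternatives were size factors by relative log expression (RLE), upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of CPM above 1 in 3 libraries, non-robust dispersions, the replicate number as a block, and each library left out in turn. Counts thinned to the total of the smallest library were an alternative added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.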

Results

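The series asked what FuHsi does in relation to the nucleolus, the compartment where ribosomal RNA is made and ribosomes are assembled, by profiling RNA in NCI-H1299 cells after its knockdown. The data are read counts per gene in 3 control and 3 knockdown libraries. The control libraries held 34306849, 34196300 and 30735547 counts, and the knockdown libraries held 27900051, 24231515 and 24265216. No row of the table or entry of the name tables carries the name FuHsi, and the labels give no gene symbol for it. The level of the target itself is not analysed here, so the knockdown was not checked against its own transcript.

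The control and knockdown libraries differed widely. Of 17223 tested genes, 5295 were higher and 5317 were lower in knockdown by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Changes of at least 2-fold were mostly rises, with 1577 genes higher and 538 lower. In the lowest of 5 equal classes of genes by mean log2 CPM, 649 were higher and 131 lower by that much, and in the highest 92 were higher and 106 lower. The 3 knockdown values lay all above or all below the 3 control values for 65.3% of tested genes, where chance gives 10%. The first principal component held 72.1% of the variance and separated the groups. Correlations of log2 CPM were 0.990 to 0.992 within groups and 0.963 to 0.969 between them. The median fold change fell with abundance, from 0.31 in the lowest of these classes to -0.20 in the highest.

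The balance of rises and falls depended on scaling. TMM factors were 0.948 ± 0.00674 in control and 1.05 ± 0.00702 in knockdown (mean ± SD, n = 3). Scaling by library size alone raised the median fold change of all genes by 0.15 log2 units. It gave 6986 genes higher and 3855 lower, so that 64.4% of called genes were higher against 49.9% with TMM. Genes lower by at least 2-fold then numbered 322. All fold changes that follow are relative to the TMM scale.

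**Figure D1:**
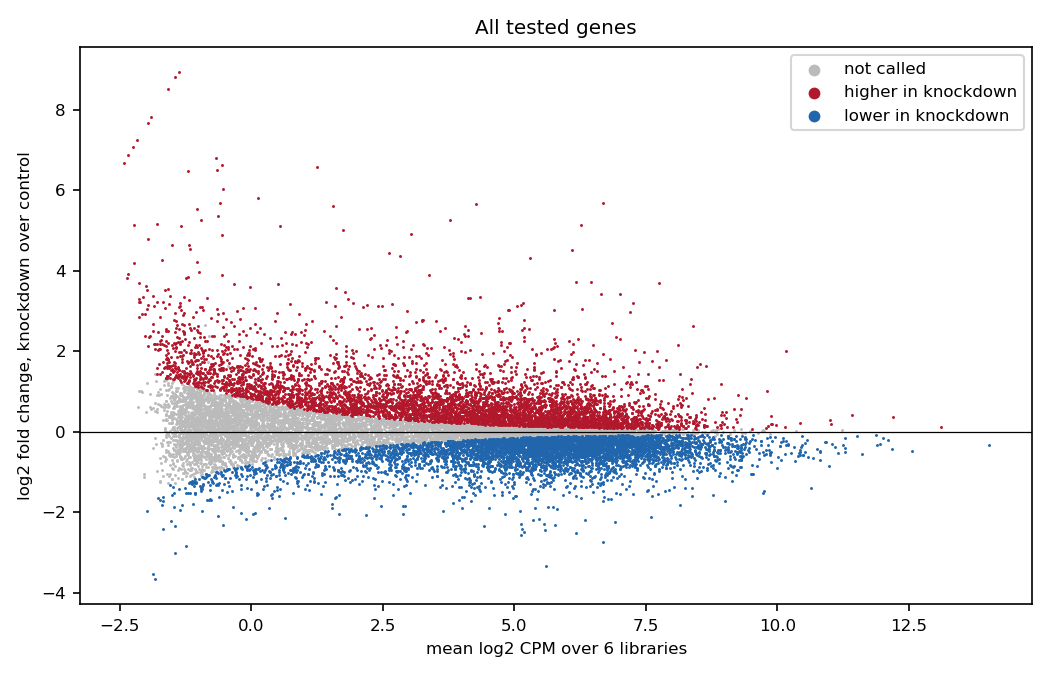
Fold change of each of the 17223 tested genes (log2, knockdown over control) against its mean log2 CPM over the 6 libraries, with 5295 genes called higher in red, 5317 called lower in blue and genes not called in grey. Rises of several log2 units stand above the bulk of genes at low and middle abundance, and abundant genes lie mostly below 0.

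Genes of the nucleolus and of ribosome assembly were mostly lower in knockdown. NPM1 (nucleophosmin, ENSG00000181163, GRCh38 chromosome 5, 171387116 to 171411137, plus strand) went from 2710 ± 25.04 to 1511 ± 53.1 CPM (mean ± SD, n = 3), a log2 fold change of -0.84. NCL (nucleolin) had a log2 fold change of -0.72. FBL (fibrillarin), the methyltransferase of box C/D particles, had one of -0.78. POLR1A, the largest subunit of RNA polymerase I, had one of -0.33. UBTF, an activator of ribosomal DNA transcription, was at 116 ± 3.35 CPM in control and 117 ± 4.96 in knockdown and was not called, with a log2 fold change of 0.01 ± 0.04 (SE) and an adjusted p of 0.837 by edgeR's quasi-likelihood test. With library size alone it was called, at 0.16.

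The decrease ran through each of the fixed lists for this compartment. Of 21 tested genes for the RNA polymerase I machinery, 13 fell and 2 rose. TCOF1 (treacle), a nucleolar factor for ribosomal DNA transcription, fell by 1.10 on the log2 scale, and TAF1D rose by 0.34. Of 52 genes for the small-subunit processome, 39 fell and 7 rose, with WDR3 at -1.86 and UTP4 at 0.41. Of 52 genes for large-subunit assembly, 39 fell and 5 rose. BOP1 fell by 1.23, and NMD3, an export adaptor of the large subunit, rose by 1.19. Of 20 snoRNP proteins, 15 fell and 2 rose, with NOLC1 at -1.83 and NOP58 at 0.64. Of 27 nucleolar structural proteins, 21 fell and 3 rose. This last list shares 3 genes with the RNA polymerase I list, 5 with large-subunit assembly and 4 with snoRNP proteins. Its result is therefore not separate from theirs. The list medians were -0.34, -0.29, -0.39, -0.42 and -0.61 in that order. By camera, the Benjamini-Hochberg adjusted p-values were 0.00165, 2.88e-06, 5.39e-07, 0.000154 and 4.17e-06. With an estimated correlation none of these 5 calls held, with adjusted p-values of 0.175 to 0.229. After removal of trends on transcript length, GC content and abundance, the medians were -0.232, -0.163, -0.317, -0.315 and -0.365. With library size alone they were -0.183, -0.140, -0.236, -0.268 and -0.453, with 13, 31, 34, 12 and 19 genes lower and 5, 11, 11, 3 and 5 higher.

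Cytosolic ribosomal protein genes shifted as a block. Of 78 tested, 75 fell and 2 rose, with a median of -0.32, and the list's share of all counts went from 4.92% ± 0.0609 to 4.29% ± 0.0291 (mean ± SD, n = 3). Most members moved by a similar amount. Falls of at least 2-fold numbered 2, RPL9 at -1.60 and a member with a mean log2 CPM under 1. RPLP2 rose by 0.39. RPL17 fell by 0.68 but shares 35.3% of its exonic bases with other genes. The camera adjusted p was 6.48e-14 for this list and 0.242 with an estimated correlation. After removal of the same trends, the list's median was 0.02 (95% bootstrap interval -0.014 to 0.065). With library size alone it was -0.169, with 63 genes lower and 3 higher.

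Other sets of the growth machinery were lower too. Of 74 mitochondrial ribosomal protein genes, 54 fell and 4 rose (median -0.35), with MRPS14 at -1.41. Of 70 nuclear genes for oxidative phosphorylation, 60 fell and 2 rose (median -0.41). ATP5F1B, a catalytic subunit of ATP synthase, fell by 1.53, and COX4I1 fell by 0.99. Of 50 splicing factor genes, 45 fell and 4 rose (median -0.39), with PRPF4 at -1.12. Camera gave Benjamini-Hochberg adjusted p-values of 1.56e-08, 6.35e-12 and 3.41e-10. With an estimated correlation the adjusted p-values were 0.202, 0.175 and 0.175. Removal of the trends on length, GC content and abundance took the medians to -0.211, -0.290 and -0.154. The 95% bootstrap interval of the splicing list was then -0.202 to -0.078. With library size alone the medians were -0.195, -0.260 and -0.238, with 41, 51 and 38 genes lower and 7, 5 and 5 higher. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 9 rose and 10 fell, with CARS1 at 1.08 and FARSA at -0.68. That list was not called, with a camera adjusted p of 0.765. Of 26 snoRNA host genes, 5 rose and 12 fell, with SNHG10 at -0.95 and a camera adjusted p of 0.107. SNHG10 shares 20.1% of its exonic bases with other genes. Small RNAs are thinly covered by such libraries, and of 23 tested snoRNA rows 3 fell and 0 rose by edgeR's quasi-likelihood test.

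**Figure D2:**
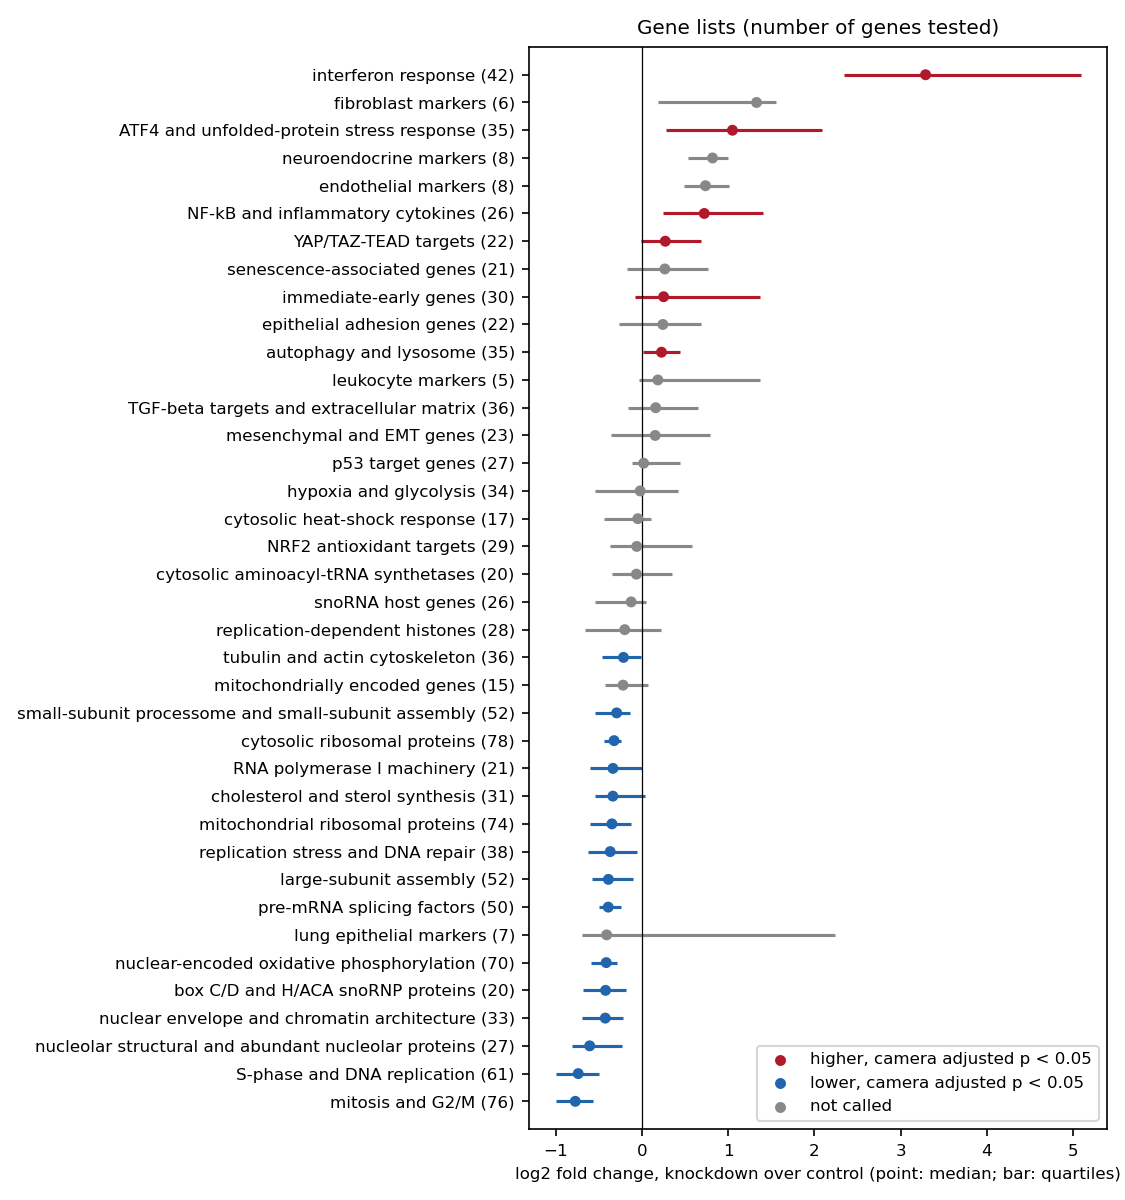
Median log2 fold change (point) and quartiles (bar), knockdown over control, of the tested members of each of the 38 gene lists, ordered by median, with lists called by camera in red (higher) or blue (lower) and others in grey. The interferon list stands apart at 3.29, and the S-phase and mitosis lists are lowest at -0.74 and -0.77.

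Interferon-response genes had the largest median rise of the 38 lists. All 42 tested members rose, with a median log2 fold change of 3.29, and the list's share of all counts went from 0.0734% ± 0.00174 in control to 0.762% ± 0.117 in knockdown (mean ± SD, n = 3). IFIT2 (chromosome 10, 89283694 to 89309276, plus strand), which binds viral RNA, went from 14.4 ± 1.17 to 744 ± 137 CPM. IFIT1 went from 13.01 ± 1.13 to 455 ± 88.1 CPM, and IFIT3 from 14.4 ± 1.70 to 328 ± 49.5 CPM. OAS1, a sensor of double-stranded RNA, rose from 0.231 ± 0.230 to 22.6 ± 3.06 CPM, a log2 fold change of 6.57 ± 0.24 (SE) with an adjusted p of 2.85e-19 by edgeR's quasi-likelihood test. Control counts of OAS1 were 2, 16 and 4, so the size of its rise is uncertain. MX1, OASL, IFI44, OAS2, SAMD9L and TRANK1, of which TRANK1 is not on the list, rose by 4.45 to 5.67 log2 units. These and the 4 genes before them are the 10 largest rises under the rule for named genes. The camera adjusted p was 7.61e-19 and became 0.241 with an estimated correlation.

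Of 26 genes for NF-kB and inflammatory cytokines, 20 rose and 3 fell (median 0.72). CSF1, a macrophage growth factor, rose by 2.72, and BIRC3, an inhibitor of cell death, rose by 2.14. SOD2, a mitochondrial antioxidant enzyme, fell by 1.88. Camera gave this list an adjusted p of 4e-05, and 0.279 with an estimated correlation. Of 30 immediate-early genes, 21 rose and 8 fell (median 0.25), with NR4A2 at 2.55 and KLF4 at 2.31. Its camera adjusted p was 0.0138, and 0.471 with an estimated correlation. Its median was 0.527 after removal of the trends and 0.405 with library size alone.

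Genes of the ATF4 and unfolded-protein stress response were higher as a group. Of 35, 29 rose and 3 fell, with a median of 1.05. SLC7A11, the cystine transporter, rose from 10.3 ± 0.528 to 83.8 ± 8.997 CPM (mean ± SD, n = 3), a fold change of 8.16. ASNS, asparagine synthetase, rose by 2.75, but shares 44.6% of its exonic bases with other genes. ASNSP1, a pseudogene of it, rose by 3.33, and reads of the pair may be split between them. PSPH and MTHFD2, of serine and folate metabolism, fell by 1.56 and 0.89, and MTHFD2 shares 33.2% of its exonic bases with other genes. The camera adjusted p was 7.77e-08, and 0.409 with an estimated correlation. Other stress lists were mixed. Of 27 p53 target genes, 12 rose and 5 fell, and the camera adjusted p was 0.297. SESN2, which is also on the ATF4 list, and PLK2 rose by 1.92 and 1.79, and TRIAP1 fell by 1.17. The line lacks p53 protein, so this list does not measure p53 activity here. CDKN1A (p21) was not called, at -0.09 with an adjusted p of 0.0704 by edgeR's quasi-likelihood test, though it passed without a filter (-0.11), and without control replicate 2, knockdown replicate 2 or knockdown replicate 3 (-0.12, -0.13 and -0.11). MDM2 was called at -0.13, and was at 0.02 with library size alone. It lost its call without control replicate 3 (-0.12) or knockdown replicate 3 (-0.11), and with upper-quartile factors (-0.07). Of 29 NRF2 targets, 12 rose and 10 fell, with HMOX1 at 3.05 and GCLM at -0.85. The median of that list was -0.06, its mean 0.26 and its camera adjusted p 0.944. Of 17 heat-shock genes, 5 rose and 8 fell, with HSPB1 at 0.89, HSPD1 at -0.61 and a camera adjusted p of 0.373. The medians of the p53, NRF2, heat-shock, aminoacyl-tRNA synthetase and snoRNA host lists were near 0 and changed sign under at least 1 scaling. Removal of the trends took those of the heat-shock, aminoacyl-tRNA synthetase and NRF2 lists to 0.247, 0.147 and 0.08.

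Cell-cycle genes were lower. Of 61 genes for S phase and DNA replication, 56 fell and 1 rose (median -0.74), and of 76 mitotic genes, 72 fell and 0 rose (median -0.77). MCM6, a subunit of the replicative helicase (chromosome 2, 135839626 to 135876426, minus strand), went from 263 ± 7.14 to 39.6 ± 2.07 CPM (mean ± SD, n = 3), 6.65-fold lower. RFC3, of the clamp loader, was at -2.41. MAD2L1 of the spindle checkpoint was at -2.49, and NCAPG2 of the condensin II complex was at -2.51. MKI67, a marker of cycling cells, fell from 795 ± 25.5 to 394 ± 22.8 CPM. TYMS was the 1 S-phase gene to rise, by 0.14. It shares 46.6% of its exonic bases with other genes and lost its call in 11 alternatives, among them the leaving out of any 1 library but knockdown replicate 3 (0.07 to 0.15). The camera adjusted p-values of these lists were 6.55e-16 and 2.38e-19, and 0.202 and 0.241 with an estimated correlation. Of 38 genes for replication stress and repair, 28 fell and 7 rose (median -0.37), with RECQL4 at -1.24 and PARP1 at -0.91. The camera adjusted p was 0.000154, and 0.175 with an estimated correlation. With library size alone the median was -0.215. Of 28 replication-dependent histone genes, 7 rose and 10 fell, with H4C8 at 0.90 and a camera adjusted p of 0.439. MYC, which drives growth and ribosome production in many cells, was slightly higher at 0.12 ± 0.03 (SE), with an adjusted p of 0.00192 by edgeR's quasi-likelihood test.

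**Figure D3:**
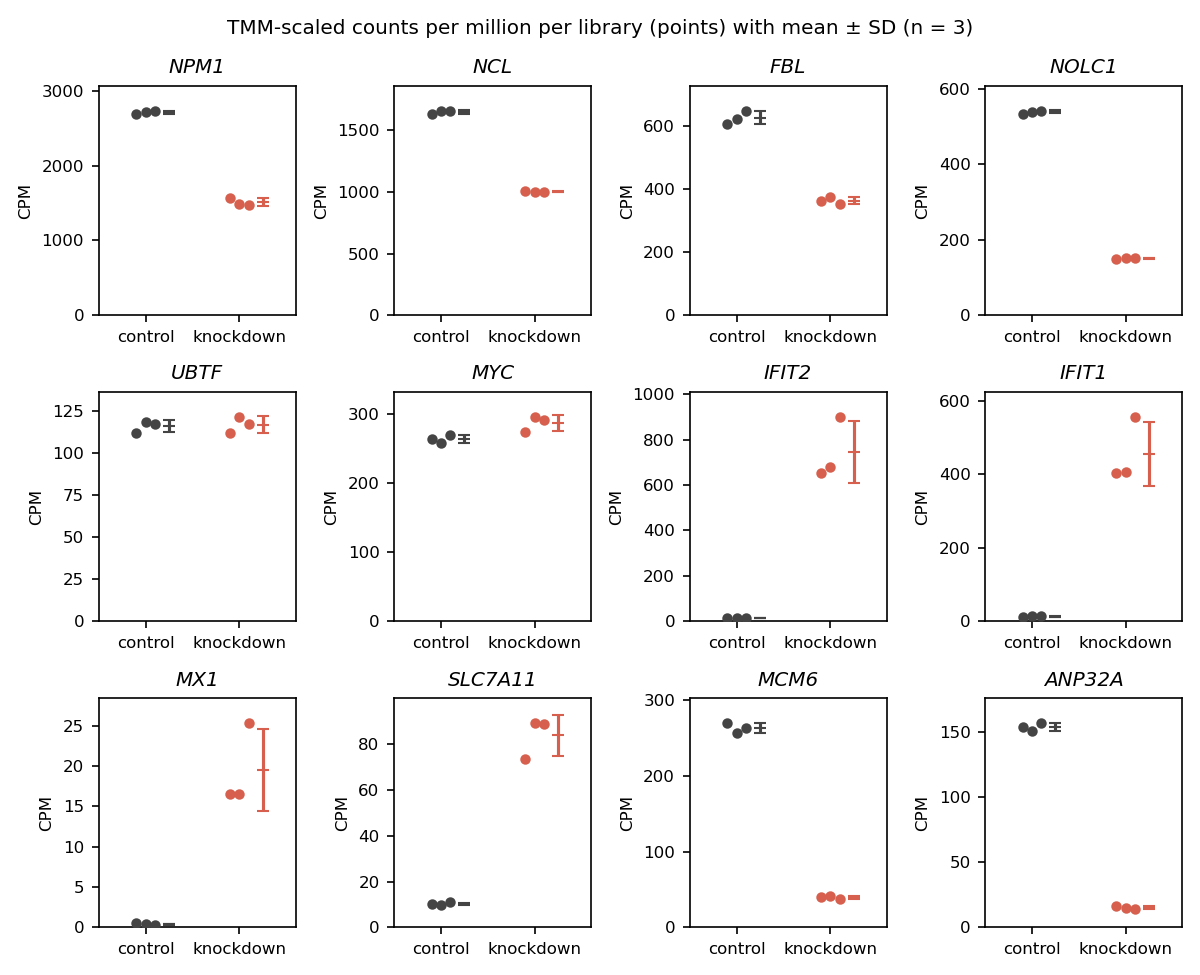
TMM-scaled CPM of 12 genes in each of the 3 control and 3 knockdown libraries (points), with the mean ± SD beside them, on linear axes that start at 0. NPM1, NCL, FBL, NOLC1, MCM6 and ANP32A are lower in every knockdown library, UBTF overlaps between groups, MYC is slightly higher, and IFIT1, IFIT2, MX1 and SLC7A11 are near the axis in control.

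Outside these groups, ANP32A (chromosome 15, 68778535 to 68820897, minus strand) had the largest fall under the rule for named genes. It encodes an acidic nuclear phosphoprotein. It went from 154 ± 3.14 to 15.1 ± 1.13 CPM (mean ± SD, n = 3), a log2 fold change of -3.35 ± 0.06 (SE) with an adjusted p of 2.07e-49 by edgeR's quasi-likelihood test. FZD6, a Wnt receptor, was at -2.58, CCM2 at -2.44, CCNE1 (cyclin E1) at -2.35, UBE2R2 at -2.32 and AIMP2 at -2.30. AIMP2 shares 28.9% of its exonic bases with other genes. Of the 10 largest falls, 8 carry the 7-base word CTATTGA, CCTATTG or ACCTATT in the 3′ UTR or coding sequence, and CCNE1 and AIMP2 do not. So do 4 of the 10 largest rises and 26.2% of the scanned genes that were not called. CTATTGA itself is in the 3′ UTR of 4 of the 10 falls and 0 of the 10 rises. Of the genes named so far, MCM6, FZD6, MAD2L1, RFC3, WDR3, NOLC1, RPL9, SOD2, PSPH, MRPS14, PRPF4 and MTHFD2, which fell, carry CTATTGA in the 3′ UTR, as do SLC7A11 and BIRC3, which rose. ACACATC, the word with the highest z in 3′ UTRs, is in those of SLC7A11, BIRC3, NR4A2 and NOP58, which rose, of UBE2R2, WDR3 and MTHFD2, which fell, and of UBTF.

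Of 2410 long non-coding genes, 638 were higher and 178 lower, and of 13331 protein-coding genes, 4286 were higher and 4976 lower. The difference between these classes was not tested at matched abundance. In the lowest of the 5 equal classes of all genes by mean log2 CPM, 721 were higher and 172 lower, with a median of 0.31, and the median of long non-coding genes was 0.29. CHILL1 rose by 2.78 and HIF1A-AS3 by 2.74. DLGAP1-AS2 fell by 1.58, LINC02609 by 1.33 and LINC00973 by 1.32. Antisense genes are uncertain because the strand setting of the counting is not known.

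Each list called by camera kept the sign of its median under all scalings, though library size alone moved many medians by over 1.5 times. On removal of the trends on length, GC content and abundance, the medians of the ribosomal protein and cytoskeleton lists changed sign, and those of the other called lists did not. Over the 38 lists, camera called 6 higher and 15 lower, and 0 with an estimated correlation; fry called 35. The counts of called genes adjusted over the list alone equalled those over all genes, with 3 exceptions. Mitosis had 73 lower, heat shock 6 higher and oxidative phosphorylation 3 higher when adjusted over the list alone.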

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

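Thinning of counts to the smallest library was chosen after seeing the data; the other settings were planned. Across all settings, the counts of genes higher, lower, and higher by at least 2-fold stayed within 1.5 times the reported values. Genes higher ranged from 4575 (DESeq2) to 6986 (library size alone), and genes lower from 3855 (library size alone) to 5401 (RLE). Genes lower by at least 2-fold numbered 322 with library size alone and 399 to 589 in the others; genes higher by at least 2-fold ranged from 1178 to 2080. Leaving out 1 library gave 4962 to 5017 genes higher and 5050 to 5198 lower. Thinning gave 5173 and 5202. Of the called genes, 86.2% were called with the same sign under library size alone, where 5 changed sign, and 88.4% to 99.6% under the others, where 0 did. DESeq2 gave no adjusted p for 11312 genes with counts.

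With the replicate number as a block, 5214 genes were higher, 5263 lower, 1564 higher by at least 2-fold and 541 lower by at least 2-fold, and no list changed its call. Deviations of same-numbered libraries from their group means correlated at -0.000751, -0.00642 and -0.0235. These values give no sign that the numbers pair the samples. They cannot exclude a weak pairing, because counting noise of low genes enters them.

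With an estimated correlation, the camera adjusted p rose to 0.175 for the RNA polymerase I, small-subunit, large-subunit and nucleolar structural lists, 0.229 for snoRNP proteins and 0.242 for cytosolic ribosomal proteins. It was 0.202 for S phase, 0.241 for mitosis, 0.241 for the interferon list and 0.409 for the ATF4 list. The estimated correlation was 0.00953 for the RNA polymerase I list and 0.0097 for the nucleolar structural list, both under the preset 0.01. This argues against a larger correlation between genes as the cause of the loss for those lists. For the other lists named here the estimate was above the preset. Camera with an estimated correlation also takes its degrees of freedom from the 6 libraries, where the preset takes them from the number of genes. Every list loses power under it, so a lost call does not by itself show correlated members. What caused each loss was not tested further. Over all lists, 418 of the tests under alternatives kept direction and side of the threshold, 21 lost the call, 13 gained it and 1 reversed. The NRF2 list was higher by fry, at an adjusted p of 0.0225, and its mean and median differ in sign. No list changed its call under library size alone, the stricter filter, thinning or the leaving out of a library. For named genes, 1616 values kept direction and call, 24 lost the call, 5 gained it and MDM2 reversed, to 0.0224 with library size alone. The losses were of MDM2, TYMS, PTPRC and CD79A, genes with small changes or few counts. Depth limits what can be said of genes under about 1 CPM.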

Other observations

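Tests of the interferon, rising-word and separate-list explanations, and the split of libraries, were chosen after the results were seen. The falling-word tests and the pooled trend test were planned.

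Among lists not yet described, 5 were lower or higher by camera. Of 33 genes for the nuclear envelope and chromatin architecture, 26 fell and 5 rose (median -0.43), with CBX3, a heterochromatin protein, at -1.53 and HMGA1 at -1.39. Of 31 genes for sterol synthesis, 21 fell and 6 rose (median -0.34), with FASN at -0.90 and STARD4, a sterol carrier, at 1.19. Of 36 cytoskeleton genes, 26 fell and 5 rose (median -0.21), with MYL12A at -1.46 and VCL (vinculin) at 1.19. Of 22 YAP/TAZ-TEAD targets, 14 rose and 3 fell (median 0.27), with CCN2 at 1.19 and AXL at -0.48. Of 35 autophagy and lysosome genes, 25 rose and 5 fell (median 0.23), with WIPI1 at 3.00. WIPI1 shares 28.1% of its exonic bases with other genes. CBX3 carries CTATTGA in its 3′ UTR, and STARD4 and WIPI1 carry ACACATC. Benjamini-Hochberg adjusted p-values by camera were 1.15e-05, 0.00194, 0.00113, 0.0102 and 0.00357 in that order. With an estimated correlation they were 0.175, 0.499, 0.471, 0.175 and 0.448. Removal of the trends on length, GC content and abundance turned the median of the cytoskeleton list to 0.084 (95% bootstrap interval -0.046 to 0.182). The medians of the other 4 lists were then -0.275, -0.219, 0.455 and 0.447. The interval of the sterol list, -0.284 to 0.043, then included 0. With library size alone the medians of the 5 lists were -0.271, -0.183, -0.060, 0.424 and 0.380, and 18 cytoskeleton genes were lower and 9 higher.

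Lists not called by camera held genes that moved both ways. Of 36 genes for TGF-beta and matrix, 18 rose and 9 fell, with SMAD6 at 1.57 and TGFBI at -1.30. Of 22 epithelial genes, 9 rose and 7 fell, with CLDN1 at 1.38 and KRT8 at -0.63. Of 23 mesenchymal genes, 12 rose and 6 fell, with ZEB2 at 1.70 and VIM at -0.70. VIM shares 24.4% of its exonic bases with other genes. Of 34 hypoxia and glycolysis genes, 13 rose and 16 fell, with SLC2A3 at 1.10 and PGAM1 at -0.89. Its median of -0.02 changed sign under other scalings and was 0.054 after removal of the trends. Of 21 senescence genes, 10 rose and 4 fell, with CDKN1B at 0.76 and HMGB2 at -0.83. Of 15 mitochondrially encoded genes, 4 rose and 10 fell, with the ribosomal RNA MT-RNR2 at 0.41 and MT-ND2 at -0.53. The median of that list went from -0.22 to 0.43 on removal of the trends. Camera adjusted p-values were 0.194, 0.529, 0.359, 0.555, 0.377 and 0.114 in that order. Many cell-type markers did not pass the count filter. Those tested were 8 of 20 neuroendocrine, 7 of 19 lung epithelial, 6 of 14 fibroblast, 8 of 12 endothelial and 5 of 20 leukocyte genes. Of the 8 tested neuroendocrine genes, 6 rose and 2 fell, with SNAP25 at 1.13 and ENO2 at -0.52. Of 7 lung epithelial genes, 3 rose and 3 fell, with LPCAT1 at -0.84, a median of -0.41 and a mean of 0.67. Of 6 fibroblast genes, 4 rose and 1 fell, with MFAP5 at 1.41, and of 8 endothelial genes, 4 rose and 1 fell, with ENG at 0.91. Of 5 leukocyte genes, 2 rose and 1 fell, with PTPRC at 1.43 and CD79A at -1.28, each at under 1 CPM. PTPRC lost its call without control replicate 2 (1.06), control replicate 3 (1.27) or knockdown replicate 2 (1.17), and CD79A without control replicate 1 (-1.07), knockdown replicate 1 (-0.95) or knockdown replicate 3 (-1.32). Camera adjusted p-values of these 5 lists were 0.107, 0.850, 0.256, 0.107 and 0.850. Of the genes in this paragraph, KRT8, MFAP5 and PTPRC carry CTATTGA in the 3′ UTR, and ZEB2, SLC2A3, SNAP25 and MFAP5 carry ACACATC.

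Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real split, the real one itself. The real split called 10612 genes and the highest of the others called 0 by edgeR's quasi-likelihood test. With 10 splits the share cannot go under 0.1. Each other split mixes control and knockdown libraries on both sides, which puts their difference into the spread within groups. Their counts are therefore not a rate of false calls.

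Falls of at least 2-fold went with a short sequence. Among all 7-base words in 3′ UTRs, CTATTGA had the lowest z, -8.50, followed by CCTATTG at -8.32 and ACCTATT at -8.02, which overlap to spell ACCTATTGA; the lowest z of 100 permutations was -4.98, and all 6 words below it belong to this family. The mean corrected log2 fold change was -0.14 for the 1064 genes with CTATTGA in the 3′ UTR, -0.25 for the 262 with CCTATTGA and -0.40 for the 65 with ACCTATTGA. At least 1 of the 3 words of 7 bases was in the 3′ UTR of 43.0% of genes lower by at least 2-fold, 21.9% of all genes lower, 19.0% of genes higher and 17.8% of genes not called, and in the 3′ UTR or coding sequence of 55.6%, 31.9%, 28.7% and 26.2%. A candidate explanation is silencing through the seed of a small RNA in the knockdown cells, such as a hairpin, though the z of CTATTGA in coding sequence, -7.10, was nearly as low, and the labels give no sequence of the reagent.

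Genes with another sequence were higher on average. ACACATC had a z of 12.99 in 3′ UTRs and 8.19 in coding sequences, against a highest permutation z of 5.24, and all 13 words above that bound belong to 1 family of overlapping words. The mean corrected log2 fold change was 0.20 for the 1178 genes with ACACATC in the 3′ UTR and 0.29 for the 418 with ACACATCA. Another word of the family, CATCAGA, had a higher z in coding sequences, 6.88, than in 3′ UTRs, 5.81. The rise of these genes could reflect a small RNA that lowers them in the control cells, or one that is lost in knockdown. The data do not separate these, and causes other than a small RNA were not tested. If either word marks a reagent, part of the difference between groups may not come from FuHsi.

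The lower nucleolar and ribosome lists were weighed against 2 explanations. Of 226 searched members of the 6 lists, only 15 carried CTATTGA in the 3′ UTR, so leaving them out could move the median little. The 211 members without it kept a median of -0.34 (95% bootstrap interval -0.40 to -0.30). At least 1 of CTATTGA, CCTATTG and ACCTATT was in the 3′ UTR or coding sequence of 61 searched members. Those without any of these words kept a median of -0.34 (interval -0.38 to -0.30). Direct matches to these words therefore cannot be the whole cause. Effects passed on from other genes that carry them were not tested. Removal of a trend with length, GC content and abundance took the pooled median of the 6 lists from -0.34 to -0.13 (interval -0.20 to -0.08), which does not decide against a bound of -0.1. With the trend fitted without the lists' members, cytosolic ribosomal protein genes came to 0.0091, so the trend may account for their fall. This cannot tell a technical trend from a real fall, because other lists that fell, such as oxidative phosphorylation, stay in the fit. The same fit took the mitochondrially encoded list from -0.22 to 0.42 (interval 0.18 to 0.72), which changed its sign. The other 5 lists pooled stayed at -0.27 (interval -0.35 to -0.20), which argues against the trend as the whole cause of the pooled fall. The small-subunit list alone, at -0.17 (interval -0.31 to -0.093), does not exclude the bound of -0.1. The intervals in this paragraph resample list members as if independent, and hold no spread between libraries or of the trend fit. An effect of the loss of FuHsi, direct or through slower growth, remains open and untested.

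The interferon response was weighed against 2 explanations. Leukocytes in the knockdown cultures would bring their abundant transcripts, but the median knockdown CPM of PTPRC, LAPTM5, CORO1A, LCP1 and CD53 was 0.475, which argues against this source. Whether the interferon genes, with a median log2 fold change of 3.29, respond to the loss of FuHsi or to the reagent that lowers it cannot be told apart. The labels name 1 knockdown reagent and no non-targeting control, and double-stranded RNA from a hairpin vector is a known inducer of these genes.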
